A study of Homo sapiens with 52 samples.

How the data were processed

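Gene expression was measured in 52 needle biopsies (18-gauge) of human kidney allografts on Illumina HT-12 v4 bead arrays, 1 array per biopsy. Per the labels, biopsies were frozen in RNAlater, RNA was isolated with TRIzol and cleaned up with a Qiagen kit, and biotin-labelled cRNA was made from 200 ng of total RNA. The labels place 9 biopsies in the group with a liver-kidney transplant and a positive crossmatch and 15 in that with a kidney alone and a positive crossmatch. With a negative crossmatch, 12 biopsies came from liver-kidney and 16 from kidney-alone transplants. All titles carry "12m", which the labels do not spell out, and whether each biopsy came from a different recipient is not stated.

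The values deposited by the authors are log2 probe intensities for 47323 probes, and they were used as deposited. The normalization software is not stated. From the values themselves, the arrays had been brought close to each other: array medians lay between 6.41 and 6.43, every array mean was 7.08 on the log2 scale, and 9 of the 52 arrays had identical sorted values within 0.005. Exact ties between arrays occurred only within 6 sets of 8 or 9 arrays, from 3 to 28 ties per pair within a set and 0 between sets. The sets are therefore called array batches, and each of the 6 held 1 to 3 biopsies of each of the 4 groups. Counts of batches below thus rest on few biopsies each. Batch differences had already been removed from the deposited values: over genes, the median F for array batch was 0.232, against 0.883 by chance. Whether that removal took the groups into account is not stated, and a block for array batch can move the estimates little after it, so array batch was weighed by the differences within batches. The deposited table gives no detection values, so signal over background is unknown.

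Probes with 1 gene symbol were used (30113 probes). XIST, TSIX and Y-linked genes (144 probes) were left out of every step. Each gene was represented by its brightest probe over all samples, and 13334 genes whose probe mean exceeded the median of all probe means (6.40, log2) were tested. Of the probes with a symbol, 30074 had a gene identifier present in the reference gene table, which served only to match names. Genome coordinates were not used. Probes without a symbol (17202) were not analysed here beyond a count of calls.

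Group means were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in 1 model of all 52 samples with no covariates. Contrasts compared liver-kidney with kidney-alone allografts within each crossmatch group and over the mean of both, positive with negative crossmatch within each transplant type, and the liver-kidney effect between the crossmatch groups. A gene counted as called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and calls with at least a 1.5-fold difference were counted beside it. For named genes, the 12 highest and 12 lowest log2 differences among called genes were taken per main contrast, or 6 and 6 for the liver-kidney crossmatch contrast, the mean contrast and the difference of effects. Where fewer than 10 genes were called, the 5 smallest p-values in each direction were taken and named as not passing. Up to 4 members with the smallest p of each list described were added.

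The gene lists (34) covered immune cells, interferon and cytokine responses, antibody-mediated rejection, endothelium, parts of the nephron, metabolism, injury and matrix, stress responses, and other cell types a core could hold, such as hepatocytes, red blood cells, muscle and fat. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation. List members called over all genes and adjusted over the list alone were counted. The groups, contrasts, lists, tests, rule for named genes and most alternatives were fixed before the data were examined.

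Chosen after seeing the data were the array batch as a block, a run without 2 arrays that stood apart from the rest, random splits of the samples without them, and a permutation test of list levels. In the last, each sample's mean log2 level over the list's genes was compared between groups, two-sided, by exact permutation where a group had 9 samples and by 100000 random permutations otherwise, adjusted over the 34 lists. The difference of the liver-kidney effects was tested with 100000 permutations of the transplant labels within crossmatch groups. Before permuting, each group's mean was subtracted and the remainders were rescaled, so that the test asked only whether the 2 effects differed. None of these permutation tests scaled a difference by the spread of the groups. Where the smaller group varied more, their p-values can be too small. Because random regroupings of the samples gave many camera calls, lists are described by the permutation test and camera is given beside it.

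The genes called between positive and negative crossmatch in kidneys alone were followed in liver-kidney allografts after splitting the positive-crossmatch kidney-alone samples in 2 at random 20 times. Calling and measuring thus used different positive-crossmatch kidney-alone samples, while the negative-crossmatch samples were not split. Where a split gave fewer than 20 called genes, the 100 with the smallest p in each direction were used. The steps were tested on simulated data. In the comparison of liver-kidney with kidney alone, 85% of genes simulated with a log2 difference of 0.5 were recovered for the positive crossmatch (13334 genes) and 87.6% for the negative crossmatch (13334 genes). For the crossmatch in kidneys alone it was 89.4% (13334 genes), and false calls were 4.84%, 4.8% and 6.44% in that order. In this simulation genes varied independently, with no outlying arrays and no structure shared between genes, so these rates need not hold for the measured data.

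Alternatives were quantile normalization, median centring of each array, no filter on dim genes, a stricter filter on dim genes, the mean of all probes per gene, and only the groups of the contrast in the fit. The others were the title number as a block, array weights, an intensity trend with robust estimation, covariates for the part of the kidney sampled, and leaving out each sample in turn. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.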

Results

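The series compared kidney allografts transplanted simultaneously with a liver with kidney allografts transplanted alone, in recipients with a positive or a negative crossmatch. A crossmatch tests whether antibodies in the recipient's serum bind the donor's cells. The 52 protocol biopsies comprised 9 liver-kidney and 15 kidney-alone allografts with a positive crossmatch, and 12 liver-kidney and 16 kidney-alone allografts with a negative crossmatch. Values are log2 intensities of 13334 genes, differences are on the log2 scale, and gene-level errors are standard errors (SE) of limma contrasts. The contrasts share groups: the negative-crossmatch kidney-alone group, for example, is the reference both for the crossmatch and for the liver-kidney transplant.

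The first contrast asked how a positive crossmatch differed from a negative one in kidneys transplanted alone, as background for the liver-kidney groups. Genes of the interferon gamma response, cytotoxic lymphocytes, macrophages, antibody-mediated rejection and endothelium were higher with a positive crossmatch. The chemokines CXCL9 and CXCL10, which draw T cells and are induced by interferon gamma, had the highest log2 differences at 2.47 (SE 0.496) and 1.90 (SE 0.37). CXCL9 was at 10.34 ± 1.59 (SD, n = 15) against 7.86 ± 1.21 (SD, n = 16). IDO1, a tryptophan-degrading enzyme, was higher by 1.44, and ACKR1, a chemokine-binding receptor of venular endothelium, by 1.53. The other 8 of the 12 highest were the lymphocyte and myeloid genes NKG7, CCL5, FCN1, RAC2, GZMA, LYZ, LCP1 and CD52, at 1.30 to 1.48.

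Of 33 interferon gamma response genes tested, 26 were called higher and 0 lower, or 30 higher when adjusted over the list alone. Among them IRF1, a transcription factor of the response, was higher by 1.14, GBP1 by 1.19 and WARS1 by 0.81. The list's mean level was 9.45 ± 0.53 (SD, n = 15) against 8.66 ± 0.31 (SD, n = 16), a difference of 0.783 (permutation adjusted p = 0.00068). The cytotoxic and NK cell list had 15 of 20 members higher (17 adjusted over the list alone), including KLRB1 at 1.30, IL2RB at 1.17 and the pore-forming protein PRF1 at 0.91. Its level differed by 0.791 (permutation adjusted p = 0.00034, from 1e-05, the smallest p these permutations can give). The macrophage and monocyte list had 15 of 27 members higher (26 over the list alone), with CD14, the lipopolysaccharide co-receptor, at 0.81 and the integrin ITGB2 at 1.16, and a list difference of 0.693 (permutation adjusted p = 0.00176).

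The antibody-mediated rejection marker list had 17 of 24 members higher (23 adjusted over the list alone), with PLA1A at 0.79 (SE 0.132). Its level differed by 0.551 (permutation adjusted p = 0.00068). The endothelial list had 10 of 24 members higher (16 over the list alone), among them the junction protein CDH5 at 0.47, the nitric oxide synthase NOS3 at 0.51 and CD34 at 0.41, and differed by 0.323 (permutation adjusted p = 0.000816). CDH5, ROBO4 and SOX7 belong to both of these lists. The T cell list had 9 of 21 members higher (11 over the list alone) and differed by 0.48 (permutation adjusted p = 0.00068), but its camera call was lost with an estimated correlation (adjusted p = 0.0837). The NF-kB and cytokine list had 5 of 21 members higher (13 over the list alone), including IL1B at 0.48, TNF at 0.74 and CCL2 at 0.89, and differed by 0.405 (permutation adjusted p = 0.00238). Type I interferon response genes had 4 of 30 members higher (11 over the list alone), such as OAS2 at 0.83 and IFI27 at 0.75, with a list difference of 0.261 (permutation adjusted p = 0.0153, adjusted p = 0.151 with an estimated correlation). With an estimated correlation, the interferon gamma (adjusted p = 0.0128), cytotoxic (0.00734), macrophage (0.034), antibody-mediated rejection (0.00248), endothelial (0.0128) and NF-kB (0.0346) lists kept their camera calls. Levels of these 6 lists were higher in 6 of 6 array batches, as were those of the T cell and type I interferon lists.

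In all, limma called 326 genes, 306 higher and 20 lower, of which 147 differed at least 1.5-fold, all of them higher. The 12 lowest were between -0.49 (RHEX) and -0.22 (STK33 and ERBIN), and the other 9 were TMEM63A, MAP3K21, ZNF385D, FGFBP3, ZBTB43, KANSL1L, BBS2, LIN52 and PLEKHH1. With the array batch as a block, 211 genes were called (208 higher), MAP3K21 and ZBTB43 kept their calls among these 12, and the higher genes ACKR1 and LYZ lost theirs. The title number as a block gave 184 genes (180 higher, 4 lower). Array weights gave 766 (622 higher, 144 lower), with all 326 among them, so the number of lower genes rested on the weighting. With the mean of all probes per gene, OAS2 stood at 0.30 and CD34 at 0.19, both still called. Leaving out 1 sample gave 176 to 498 genes, of which 3 to 62 lower, and 3 kidney-alone samples each moved the count by more than 1.5 times.

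**Figure D1:**
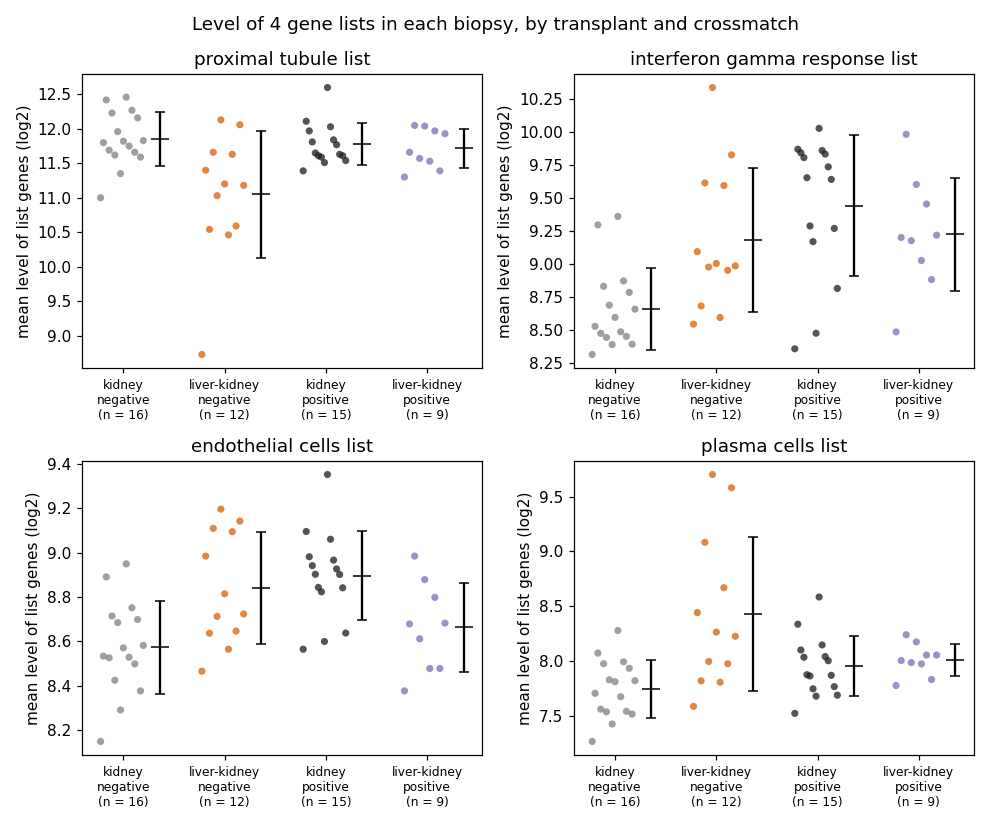
Mean level (log2) of the genes of 4 lists in each biopsy, by transplant and crossmatch. Each point is 1 biopsy, and the bar beside each group marks its mean and SD. The proximal tubule list averages 11.05 in negative-crossmatch liver-kidney allografts and 11.85 in kidneys alone, and the interferon gamma list averages 9.45 in positive-crossmatch and 8.66 in negative-crossmatch kidneys alone.

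The next contrast asked whether kidneys transplanted with a liver differed from kidneys alone when the crossmatch was positive. The endothelial and antibody-mediated rejection lists lay below the kidney-alone level, but neither passed adjustment over the 34 lists. The endothelial list was at 8.66 ± 0.20 (SD, n = 9) against 8.90 ± 0.20 (SD, n = 15), a difference of -0.233 (exact permutation p = 0.0117, adjusted p = 0.396). Within it SOX7 differed by -0.23, ROBO4, a receptor of vascular endothelium, by -0.30, CDH5 by -0.33 and EMCN by -0.32, and these 4 passed when adjusted over the list alone. The antibody-mediated rejection list differed by -0.304 (exact permutation p = 0.0413, adjusted p = 0.469), with 9 of 24 members lower when adjusted over the list alone and PLA1A at -0.46. Both lists were lower in 5 of 6 array batches, and their camera calls (adjusted p = 2.21e-09 and 9.85e-12) were lost with an estimated correlation (adjusted p = 0.372 and 0.333).

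The interferon gamma list differed by -0.218 in the mean and by -0.455 in the median over samples (exact permutation p = 0.308, adjusted p = 0.747), with IDO1 at -0.89 and WARS1 at -0.40, neither passing. The type I interferon list differed by 0.164 in the mean and by -0.128 in the median over samples (exact permutation p = 0.25, adjusted p = 0.747), with RIGI at 0.27 and MX1 at 0.49, neither passing. The dendritic cell list differed by -0.193 (exact permutation p = 0.0254, adjusted p = 0.432). Neither the proximal tubule list (-0.0628 in the mean, 0.0064 in the median over samples, exact permutation p = 0.632) nor the T cell list (0.0409, exact permutation p = 0.787) passed.

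By limma, 0 of 13334 genes were called in this contrast, 1074 genes had an unadjusted p under 0.05 against 667 by chance, and the smallest adjusted p was 0.269. The 5 smallest p-values among higher genes belonged to LRCH3 (0.31), CTNND1 (0.26), FOXO3 (0.42), SLC35E1 (0.47) and KAT2A (0.38), none passing. CTNND1 and FOXO3 each had another probe of the opposite sign, at -0.05 and -0.07. With the mean of all probes per gene, CTNND1 stood at 0.08, FOXO3 at 0.17 and SLC35E1 at 0.18. Among lower genes they belonged to COQ2 (-0.29), the macrophage chemokine CCL3 (-0.65), ERCC1 (-0.26), PSMC4 (-0.41) and WDR31 (-0.21), none passing. ERCC1, PSMC4 and SOX7 stood at -0.16, -0.26 and -0.15 with the mean of all probes. CCL3 has close relatives in the genome, and its probe may not tell them apart.

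Genes called for the crossmatch in kidneys alone were then measured in positive-crossmatch liver-kidney allografts. The 2 contrasts share the positive-crossmatch kidney-alone samples, so those used to call and those used to measure were kept apart over 20 random splits. The genes' median difference between liver-kidney and held-out kidney-alone samples was -0.0976 (range -0.257 to -0.0147), below 0 in 20 of 20 splits. For the genes called higher it was -0.191 (range -0.335 to -0.0145), where held-out kidneys alone exceeded the negative crossmatch by 0.648 and liver-kidney allografts exceeded it by 0.432. The same negative-crossmatch kidneys served to call the genes and as this reference, so the choice of genes can inflate both excesses. Calls were made in a fit of the kidney-alone samples only, which without splitting gave 438 genes (309 of them among the 326), and the median over these was -0.149. Of 100 shuffles of the labels, 10 gave a median as low or lower, so the difference was not beyond chance. In 6 of the 20 splits too few genes passed, and the 100 smallest p-values in each direction were used. A simulated difference of -0.5 was recovered as -0.482 (200 of 13334 genes simulated).

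With a negative crossmatch, kidneys transplanted with a liver had lower levels of proximal tubule genes and higher levels of plasma cell, T cell and cytotoxic cell genes than kidneys alone. The proximal tubule list was at 11.05 ± 0.92 (SD, n = 12) against 11.85 ± 0.39 (SD, n = 16), a difference of -0.801 (permutation adjusted p = 0.0081). The smaller group varied more here, so this p can be too small. Of the list's 36 members, 31 were called lower (35 adjusted over the list alone). Among them were the fatty acid hydroxylase CYP4A11 at -0.89, the urate transporter SLC22A12 at -0.97, FBP1, an enzyme of gluconeogenesis, at -0.84, and the phosphate and urate transporter SLC17A3 at -1.29. The single genes with the lowest log2 differences were CYP27B1, which makes active vitamin D, at -1.63 (SE 0.436), and the glucuronidation enzymes UGT1A9, UGT1A10 and UGT1A7 at -1.53, -1.49 and -1.44. The remaining 8 of the 12 lowest were SLC17A3, the detoxifying enzymes GSTA1 and GSTA2, CYP4F2, HPD, G6PC1, the final enzyme of glucose release, PRODH2 and CRYAA, at -1.40 to -1.17. UGT1A transcripts share exons and GSTA1 and GSTA2 are similar in sequence, so each family counts as 1 signal rather than several.

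Amino acid and organic acid metabolism genes were lower in 38 of 42 members (40 adjusted over the list alone), with QPRT at -0.69 and MCCC2 at -0.41 and a list difference of -0.543 (permutation adjusted p = 0.00768). Fatty acid oxidation and peroxisome genes were lower in 25 of 32 members (27 over the list alone), with AMACR at -0.79 and ECHS1 at -0.69, and differed by -0.42 (permutation adjusted p = 0.00589). The hepatocyte list, included as a marker of another tissue, differed by -0.317 (permutation adjusted p = 0.00589), with 4 of 14 members lower, among them SERPINC1 at -0.68 and APOH at -0.73. Whether the fall of the hepatocyte list was separate from that of the proximal tubule list was not tested. These 4 lists were lower in 6 of 6 array batches.

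On the higher side, IGLL1, a surrogate light chain gene of precursor B cells, had the highest difference at 3.15 (SE 0.61), from 9.17 ± 1.64 (SD, n = 16) to 12.32 ± 1.98 (SD, n = 12). With the mean of all its probes in place of the brightest, the IGLL1 difference was 1.05, still called. IGLL1 resembles the lambda light chain genes in sequence, and its probe may not tell them apart. JCHAIN, which joins immunoglobulin units, was higher by 2.28 and MZB1, a plasma cell secretory protein, by 1.27. The plasma cell list had 9 of 10 members higher (9 higher and 1 lower adjusted over the list alone), CD38 at 0.68 among them, and differed by 0.683 (permutation adjusted p = 0.00589). The T cell list had 11 of 21 members higher (13 adjusted over the list alone), with CD3D at 1.28 and CD2 at 1.03, and differed by 0.478 (permutation adjusted p = 0.00768). The cytotoxic list had 8 of 20 members higher (9 over the list alone), with CCL5 at 1.23 and GZMA at 1.18, and differed by 0.482 (permutation adjusted p = 0.0103). The size of these 2 differences varied with the processing: the median over members was 0.401 for T cells (range 0.208 to 1.02 over the alternatives) and 0.425 for cytotoxic cells (range 0.203 to 0.88). The endothelial list had 6 of 24 members higher (11 over the list alone), with ENG at 0.57 and PECAM1 at 0.46, and differed by 0.268 (permutation adjusted p = 0.0166). The other 6 of the 12 highest were CCL19, CD52, HCST, RAC2, LYZ and HLA-DRB6, at 1.19 to 1.43.

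The interferon gamma list had 17 of 33 members higher (24 adjusted over the list alone), with IRF1 at 0.90 and TAPBP at 0.66, another probe of which lay at -0.01, and differed by 0.524 (permutation adjusted p = 0.011). The macrophage list had 15 of 27 members higher (21 over the list alone), with CSF1R at 0.79 and C1QC at 0.89, and differed by 0.558 (permutation adjusted p = 0.0219). The matrix and fibroblast list had 9 of 31 members higher (13 over the list alone), with PDGFRB at 0.52 and TNC, a matrix protein of wounds, at 1.14, and differed by 0.407 (permutation adjusted p = 0.042). The plasma cell, T cell, cytotoxic, endothelial, interferon gamma and macrophage lists were higher in 5 of 6 array batches, and the matrix list in 4 of 6. Markers of other kidney segments did not pass adjustment. They differed by 0.059 for the loop of Henle, -0.0546 for the distal tubule and collecting duct and -0.0419 for podocytes (permutation adjusted p = 0.801, 0.723 and 0.723). The medians over samples had the opposite sign for the loop of Henle (-0.00427) and the collecting duct (0.0306). With an estimated correlation no list kept its camera call in this contrast (smallest adjusted p = 0.233).

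By limma 2106 genes were called, 1022 higher and 1084 lower, of which 169 higher and 212 lower differed at least 1.5-fold, and 1643 were called with the array batch as a block. Array weights gave 1309 genes and a fit of the contrast's groups alone 1233. In 2 of the 12 negative-crossmatch liver-kidney biopsies the median correlation with other arrays was 0.927 and 0.949, against a middle value of 0.975, and without them 101 genes were called (36 higher, 65 lower), all among the 2106. Without them, the lists kept at an adjusted permutation p under 0.05 included proximal tubule (-0.523, 0.0479), amino acid metabolism (-0.366, 0.0479), fatty acid oxidation (-0.305, 0.0326), hepatocyte (-0.26, 0.0326), plasma cell (0.49, 0.0338), T cell (0.299, 0.0479), cytotoxic (0.354, 0.0479) and endothelial (0.257, 0.0479). The interferon gamma (0.344, 0.0624), macrophage (0.351, 0.128) and matrix (0.291, 0.179) lists were not kept. With the mean of all probes per gene, CD3D stood at 0.81, MZB1 at 0.72 and TAPBP at 0.26, all still called, and with array weights JCHAIN stood at 1.5 and lost its call. Of the 43 genes named for this contrast, 29 lost their calls without the 2 biopsies, and of these CRYAA (-0.66), GSTA1 (-0.81), GSTA2 (-0.86), HPD (-0.84), PRODH2 (-0.70) and LYZ (0.68) moved by more than 1.5 times. The 14 that kept them were IGLL1, MZB1, UGT1A7, UGT1A9, UGT1A10, CYP4A11, SLC22A12, FBP1, QPRT, MCCC2, AMACR, ECHS1, TAPBP and ENG. Leaving out 1 sample gave 1055 to 2797 genes, and 2 liver-kidney samples each moved the count by more than 1.5 times.

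**Figure D2:**
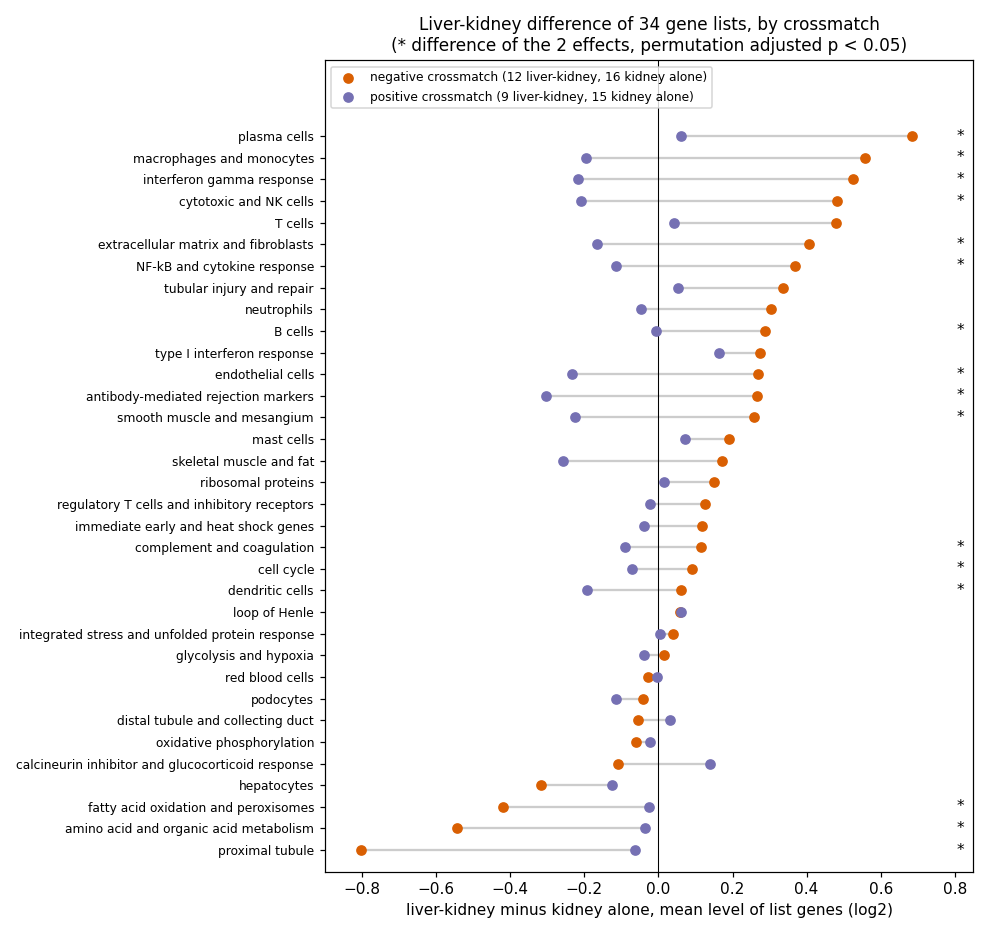
Difference in mean level (log2) between liver-kidney and kidney-alone allografts for each of the 34 lists, with a negative crossmatch (12 and 16 biopsies) and a positive crossmatch (9 and 15 biopsies). Lines join the 2 differences of a list, and an asterisk marks lists whose 2 differences differed at a permutation adjusted p under 0.05. The endothelial list stands at 0.268 with a negative and -0.233 with a positive crossmatch.

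Whether the liver-kidney difference depended on the crossmatch was tested directly as a difference of the 2 effects. The liver-kidney difference of the endothelial list depended on the crossmatch, with a difference of effects of -0.501 (permutation adjusted p = 0.00102). It was 0.268 with a negative crossmatch, which passed adjustment, and -0.233 with a positive one, which did not (adjusted p = 0.396). Of its members, 18 of 24 were lower and 1 higher when adjusted over the list alone, and CDH5 (-0.68), ENG, a co-receptor of the TGF-beta family (-0.69), PECAM1 (-0.80) and ROBO4 (-0.53) did not pass over all genes. The antibody-mediated rejection list had a difference of effects of -0.569 (permutation adjusted p = 0.0068), with 17 of 24 members lower adjusted over the list alone. Without the 2 biopsies that stood apart, both remained, at -0.49 (adjusted p = 0.00204) and -0.517 (adjusted p = 0.0306). The interferon gamma list had a difference of effects of -0.742 (permutation adjusted p = 0.0179), with IRF1 at -1.15, not passing, and the proximal tubule list of 0.738 (permutation adjusted p = 0.0179). Without the 2 biopsies they were -0.562 (adjusted p = 0.116) and 0.46 (adjusted p = 0.119). Camera calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.201, 0.201, 0.226 and 0.226).

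At the gene level limma called 0 of 13334 genes for the difference of effects, 2344 genes had an unadjusted p under 0.05 against 667 by chance, and the smallest adjusted p was 0.0603. The smallest p-values among lower genes belonged to HLA-E, a non-classical HLA class I gene (-0.94), the elastic fibre protein EMILIN1 (-0.69), RAPGEF5 (-0.71), the prostaglandin receptor PTGER4 (-0.74) and ADPRM (-0.40). Among higher genes they belonged to LIN52 (0.51), NUDT9 (0.39), BEND7 (0.68), INAVA (0.58) and HCN3 (0.43). None of these passed, and BEND7 stood at 0.27 with the mean of all probes. With covariates for the part of the kidney sampled, 420 genes were called (99 higher, 321 lower), and with the title number as a block 112. Leaving out 1 sample gave 0 to 195 genes, with 10 samples whose omission gave any call.

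Across the 13334 genes, which are not independent replicates, the liver-kidney differences in the 2 crossmatch groups were nearly unrelated (Pearson r = 0.0377, Spearman rho = 0.0703). Shuffled transplant labels gave r between -0.471 and 0.434, and 90 of 100 arrangements, the real one included, gave r as far from 0. At an unadjusted p under 0.05, 157 genes were higher in both against 95.9 by chance, and 84 were lower in both against 73.7. In opposite directions, 26 genes were higher with a positive and lower with a negative crossmatch against 89.2 by chance, and 64 the other way round against 79.3. These overlaps were not tested.

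Within liver-kidney allografts, a positive crossmatch was compared with a negative one. Proximal tubule genes stood at a difference of 0.664 (exact permutation p = 0.0366, adjusted p = 0.334), with 28 of 36 members higher when adjusted over the list alone. SLC17A1, G6PC1 and SLC17A3 differed by 0.97, 1.09 and 1.03, none passing over all genes. The amino acid list differed by 0.424 (exact permutation p = 0.0394), the fatty acid oxidation list by 0.267 (exact permutation p = 0.0397) and the smooth muscle and mesangium list by -0.339 (exact permutation p = 0.0144), each at an adjusted p of 0.334. The interferon gamma list differed by 0.0415, with a median over genes of -0.0149 (exact permutation p = 0.853) and the antibody-mediated rejection list by -0.018 (exact permutation p = 0.873). Without the 2 biopsies that stood apart, the proximal tubule difference was 0.385 (exact permutation adjusted p = 0.481). Camera called 11 lists at the preset correlation, among them proximal tubule (adjusted p = 5.19e-23), plasma cell (0.0019) and matrix (0.000225). None kept its call with an estimated correlation (smallest adjusted p = 0.445).

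Limma called 0 of 13334 genes within liver-kidney allografts, 1643 had an unadjusted p under 0.05 against 667 by chance, and the smallest adjusted p was 0.138. The smallest p-values belonged to UGT1A9 (1.45), UGT1A7 (1.30), UGT1A10 (1.33), NUDT9 (0.32) and INAVA (0.45) among higher genes and to ARF5 (-0.32), UBTF (-0.25), ADPRM (-0.30), LDB2 (-0.48) and IFRD1 (-0.29) among lower genes, none passing. IFRD1 stood at -0.12 and UBTF at -0.06 with the mean of all probes. Leaving out 1 sample gave 0 to 8 genes, with 3 liver-kidney samples whose omission gave any call.

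Averaged over both crossmatch groups, liver-kidney allografts had lower levels of CYP27B1 (-1.33, SE 0.324), G6PC1 (-0.76), SLC17A3 (-0.74), UGT1A10 (-0.73), UGT1A9 (-0.71) and the glucose transporter SLC5A2 (-0.69). Higher were IGLL1 (1.99), JCHAIN (1.35), MZB1 (0.67), the protease inhibitor SLPI (0.64), IFI44L (0.56) and the kinase PIM2 (0.52). CYP27B1 was at 9.34 ± 0.93 (SD, n = 9) against 10.36 ± 1.15 (SD, n = 15) with a positive crossmatch and at 8.92 ± 1.12 (SD, n = 12) against 10.56 ± 1.37 (SD, n = 16) with a negative one. An average need not hold in both groups: those of UGT1A9, UGT1A10 and MZB1 came almost wholly from the negative crossmatch. The proximal tubule list differed by -0.801 with a negative and -0.0628 with a positive crossmatch, and the plasma cell list by 0.683 and 0.0602. Of 30 type I interferon genes 4 were higher (15 adjusted over the list alone), among them MX1 at 0.51, SAMD9 at 0.33 and XAF1 at 0.35, and 6 of 36 proximal tubule genes were lower (27 over the list alone), FBP1 at -0.61 and CYP4A11 at -0.53 among them. KRT19, a keratin of injured tubules, was higher by 0.43. Camera called these 2 lists with a preset correlation (adjusted p = 8.37e-09 and 3.81e-15) but not with an estimated one (adjusted p = 0.539 and 0.449).

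In this average limma called 521 genes, 271 higher and 250 lower, of which 19 differed at least 1.5-fold (4 higher, 15 lower). With the array batch as a block 198 were called, without the 2 biopsies that stood apart 117, of which 115 were among the 521, and with the title number as a block 0. Of the 18 genes named here, 15 lost their calls without the 2 biopsies, and IGLL1, FBP1 and CYP4A11 kept theirs. With the mean of all probes per gene, IGLL1 stood at 0.67 and MZB1 at 0.40, both still called. Leaving out 1 sample gave 144 to 949 genes, and 20 samples each moved the count by more than 1.5 times.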

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

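The tests of the arrays that stood apart, of medulla, of the share of proximal tubule and of array batch, the random splits without the 2 arrays, and the permutation of list levels, were chosen only after the result was seen.

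The liver-kidney effect differed between the crossmatch groups for 16 of the 34 lists (permutation adjusted p under 0.05, positive minus negative crossmatch). Lower with a positive crossmatch were the differences for the endothelial (-0.501), antibody-mediated rejection (-0.569), interferon gamma (-0.742), cytotoxic (-0.692), macrophage (-0.752), plasma cell (-0.622), matrix and fibroblast (-0.573), smooth muscle and mesangium (-0.484), NF-kB (-0.482), B cell (-0.294), dendritic cell (-0.255), complement (-0.206) and cell cycle (-0.163) lists. Higher were those for the proximal tubule (0.738), amino acid (0.508) and fatty acid oxidation (0.394) lists. Without the 2 arrays that stood apart, the endothelial and antibody-mediated rejection lists stayed under an adjusted p of 0.05, and the smallest adjusted p of the other 14 was 0.116. With an estimated correlation no list kept its camera call for this difference (smallest adjusted p = 0.201).

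The liver-kidney difference of the endothelial list depended on the crossmatch: it was 0.268 with a negative crossmatch and -0.233 with a positive one, where it did not pass adjustment (adjusted p = 0.396). A candidate explanation is a different number of glomeruli, which are rich in endothelium, in the cores. With the podocyte level as a covariate the difference of effects was -0.505 (SE 0.115) and the positive-crossmatch difference -0.269 (SE 0.0863). Without the 2 arrays that stood apart, the former was -0.515 (SE 0.118). The covariate made neither smaller (-0.501 and -0.233 without it), although podocyte genes were themselves lower in positive-crossmatch liver-kidney allografts (-0.114). Within groups, endothelial levels thus did not rise with podocyte levels, so the covariate cannot decide on glomeruli. Shifts common to a batch of arrays, or their removal before deposit, leave differences within the batch as they are. Within batches the list was lower in 5 of 6 with a positive crossmatch (mean -0.189) and higher in 5 of 6 with a negative one (mean 0.277). The smallest of these differences were near 0, at -0.00528 and 0.00704, and some batches held only 1 positive-crossmatch liver-kidney biopsy. The difference of effects within batches had a mean of -0.466 (SE 0.156 over the 6 batches), which argues against such shifts as its whole. For the positive crossmatch alone, the SE of 0.0794 over 6 batches is too wide to decide. The number of glomeruli, recipient selection and an effect of the transplanted liver on the kidney's endothelium stay open as hypotheses. So does a lower share of proximal tubule for the rise with a negative crossmatch. The pattern was found and tested on the same data.

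The proximal tubule list was lower in negative-crossmatch liver-kidney allografts. Without the 2 arrays that stood apart the difference was -0.523 (SE 0.159), so they account for part of it but not the whole. More medulla in the cores would raise loop and collecting duct markers, whose mean difference was -0.0145 (SE 0.0969), or 0.0826 (SE 0.0926) without the 2 arrays, which argues against it as the whole. RNA quality is not given in the labels and could not be tested, and tubular loss, recipient selection and an effect of the liver stay open, as untested.

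The T cell and interferon gamma lists were higher in the same allografts. A lower share of proximal tubule would raise every other cell type alike, and these lists exceeded the loop, collecting duct and podocyte lists by 0.514 (SE 0.214). Without the 2 arrays that stood apart the excess was 0.255 (SE 0.192), so a lower tubular share stays open. More immune cells in the biopsies may account for it too, untested, and without the 2 arrays the interferon gamma list had a permutation adjusted p of 0.0624.

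Regrouping the samples at random gave 99 other splits per contrast. For called genes, 1 of 100 splits, the real one, reached 2106 in the negative-crossmatch liver-kidney contrast (highest other 145). In the crossmatch contrast of kidneys alone, 1 of 100 reached 326 (highest other 1). Chance is thus unlikely for both with all samples, but 100 splits cannot exclude it. When the 2 arrays that stood apart were left out, 3 of 100 splits reached the 101 genes of the negative-crossmatch liver-kidney contrast (highest other 573). Chance is thus unlikely there but not excluded, and the 573 points to structure among the samples that can give more calls than the transplant. For the mean contrast 3 of 100 reached 521, and 1 random split gave 964, which points to the same. With these arrays left out, 1 of 100 reached the 117 genes of that contrast (highest other 0). Chance is thus unlikely for the mean contrast with or without these arrays, but 100 splits cannot exclude it in either. For the contrasts with 0 calls all 100 splits reached the real count, with highest other counts of 1 for the positive-crossmatch liver-kidney contrast, 49 for the crossmatch within liver-kidney allografts and 1 for the difference of effects. The 49 also points to structure among the samples.

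Camera lists called at a preset correlation were common in random splits, whose medians lay between 10 and 13 lists. Chance is unlikely for the crossmatch contrast of kidneys alone (23 lists, 2 of 100 splits), but not excluded, since a random split gave more lists (highest other 24). More splits reached the real count for liver-kidney against kidney alone, so chance cannot be excluded with a positive crossmatch (9 lists, 62 of 100 splits, highest other 22), with a negative crossmatch (20 lists, 12 of 100, highest other 29) or on average (14 lists, 43 of 100, highest other 25). Nor can it for the crossmatch within liver-kidney allografts (11 lists, 62 of 100, highest other 23) or the difference of effects (19 lists, 14 of 100, highest other 24).

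In the group of 9 biopsies, 1 biopsy lay far from the others for CCL3 (gap over range 0.507), 1 for IFI44L (0.526) and 1 for the mast cell list (0.505), each above the critical value of Dixon's test. These were 3 of 70 values tested, and chance gives about 1 in 20.

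Among 6079 probes with no gene name that passed the level filter, 385 were called for liver-kidney against kidney alone with a negative crossmatch (151 higher, 234 lower), 9 for the crossmatch in kidneys alone (9 higher) and 191 on average over crossmatch groups (119 higher, 72 lower). They were not analysed further.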

How the results depend on the processing

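The array batch as a block and the run without the 2 arrays that stood apart were chosen after seeing the data. Among lists called by camera and named genes that were called, 1 changed direction under the alternatives run. This was the oxidative phosphorylation list in the negative-crossmatch liver-kidney contrast, which moved from a median of -0.0737 to 0.00243 without these 2 arrays. For named genes that did not pass, a change of direction was recorded only where the alternative called the gene, so their directions were not fully checked. Quantile normalization, median centring and the trend with robust estimation left every count of called genes within 1.5 times. Counts moved further as follows, and the cause was not tested. For liver-kidney against kidney alone with a positive crossmatch, the mean of all probes per gene gave 1 gene. With a negative crossmatch, only the groups of the contrast gave 1233, array weights 1309 and the run without the 2 arrays 101. For the crossmatch in kidneys alone, a stricter filter on dim genes gave 196 (fewer genes tested), the title number as a block 184, array weights 766 and the array batch as a block 211. For the crossmatch within liver-kidney allografts, the title number as a block gave 8. For the mean contrast, no filter on dim genes gave 333, the title number as a block 0, array weights 251, covariates for the part of the kidney sampled 245, the array batch as a block 198 and the run without the 2 arrays 117. For the difference of effects, the mean of all probes gave 7, the title number as a block 112, array weights 9 and the covariates for the part of the kidney 420.

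The sizes of list differences moved as well: the median over T cell members ranged from 0.208 to 1.02 with a negative crossmatch and from 0.251 to 1.14 for the crossmatch in kidneys alone, and over cytotoxic members from 0.203 to 0.88 and from 0.433 to 1.23. The highest values came from the stricter filter on dim genes, which keeps fewer members.

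Leaving out each sample in turn gave 1055 to 2797 genes with a negative crossmatch, 176 to 498 for the crossmatch in kidneys alone, 0 to 8 for the crossmatch within liver-kidney allografts, 144 to 949 for the mean contrast, 0 to 195 for the difference of effects, and 0 throughout with a positive crossmatch. Of the 41 genes named for the crossmatch in kidneys alone, 12 lost their calls on leaving out some sample, as did 10 of 43 with a negative crossmatch and 14 of 18 in the mean contrast. The numbers in the titles do not pair the samples: over 66 pairs with the same number the mean correlation was -0.0319, and 2 samples correlated best with their own number. The median difference of crossmatch genes in liver-kidney allografts lay between -0.0976 and -0.0681 over the choices tried, and the correlation of the 2 liver-kidney effects between 0.0302 and 0.0845. The table gives no background or detection values, so how far dim genes limit the counts is unknown.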

Other observations

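Ribosomal protein genes were higher in negative-crossmatch liver-kidney allografts than in kidneys alone, by 0.151 (permutation adjusted p = 0.0159), in 6 of 6 array batches, with 12 of 40 members called higher and 1 lower, and without the 2 arrays that stood apart the difference was 0.126 (adjusted p = 0.0702). Tubular injury and repair genes were higher by 0.337 (permutation adjusted p = 0.042), NF-kB and cytokine genes by 0.368 (0.0159), type I interferon genes by 0.273 (0.0219), B cell genes by 0.287 (0.0204), antibody-mediated rejection markers by 0.265 (0.0219), regulatory T cell genes by 0.127 (0.0288), neutrophil genes by 0.305 (0.0489) and immediate early and heat shock genes by 0.119 (0.042). Without the 2 arrays, none of these 8 kept an adjusted p under 0.05. The other lists did not pass in that contrast: smooth muscle and mesangium (0.259), mast cells (0.19), complement (0.116), cell cycle (0.0919), dendritic cells (0.0615), stress and unfolded protein response (0.0394), red blood cells (-0.0291), oxidative phosphorylation (-0.0612), calcineurin inhibitor and glucocorticoid response (-0.109) and skeletal muscle and fat (0.171). For glycolysis and hypoxia the mean difference was 0.0152 and the median over genes -0.0926. Few members were called higher in the regulatory T cell (2 of 9), neutrophil (1 of 8) and immediate early (4 of 26, with 1 lower) lists. Camera did not call these lists even at the preset correlation (adjusted p = 0.14, 0.0939 and 0.0668).

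In kidneys alone, a positive crossmatch also went with higher dendritic cell (0.237, permutation adjusted p = 0.00319), complement (0.189, 0.0202), regulatory T cell (0.152, 0.00574), B cell (0.184, 0.0153), neutrophil (0.28, 0.0297) and cell cycle (0.0834, 0.0488) lists. With an estimated correlation the dendritic cell (adjusted p = 0.0369) and complement (0.0491) lists kept their camera calls and the other 4 did not. The plasma cell list differed by 0.204 (permutation adjusted p = 0.095) and the red blood cell list by -0.316 (0.132), neither passing. The hepatocyte list differed by 0.051 (permutation adjusted p = 0.579) and the proximal tubule list by -0.0748 (0.654).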
